A study of Mus musculus with 23 samples.

How the data were processed

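Gene expression was measured by poly(A) RNA sequencing in epithelial cells of the medial small intestine of CD1 mice. Per the labels' protocols, epithelium was loosened with EDTA, cells were sorted by Epcam and CD44, and libraries used a stranded mRNA kit. The labels name CD44-positive cells crypt and CD44-negative cells villus, and give 3 replicates for each population at postnatal days 0, 3, 6 and 10. For P6 villus 2 libraries were analysed here. The labels do not say whether replicates are separate animals, litters or pools, nor whether a replicate number marks animals shared between populations.

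The deposited values are read counts per gene symbol. Trim Galore, STAR, HTSeq and the mouse build mm9 are named, without versions or settings, per the submitters' processing notes. Whole numbers, totals that differ between libraries and summary lines in HTSeq's layout show that no normalization had been applied. The strand setting of the counting and the treatment of reads with several alignments are not stated. Each library listed 47593 symbols and 5 summary lines, which were left out of totals and tests. Reads outside any gene made up 6.80% to 13.5% of all those listed, and mitochondrially encoded genes held 2.98% to 12.4% of the counts. This share moved with the groups, with means of 4.37% ± 1.34 (SD, n = 3) in P0 crypt, 9.16% ± 3.52 in P0 villus, 7.96% to 10.5% in the P3 and P6 groups, and 3.64% ± 0.582 and 4.26% ± 0.82 in P10 crypt and villus. As the libraries carry no molecular identifiers, intervals and floors given with counts cover counting error only. No coordinates are given, as the reference annotation has another build than the counts. It served only for the GC content and length of transcripts, matched by symbol for 98.76% of the tested genes.

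Genes were tested with edgeR 4.0.16 in R 4.3.3 and kept by filterByExpr on group with a minimum count of 10 and a minimum total of 15, which left 16535. Libraries were scaled by TMM (factors 0.734 to 1.31). A robust quasi-likelihood model with a coefficient per group was fitted over all 23 libraries (15 residual degrees of freedom, common dispersion 0.0622). In all 13 contrasts were tested by edgeR's quasi-likelihood F test, with Benjamini-Hochberg adjustment over genes within each and a threshold of 0.05. They were crypt against villus at each age, P10 against P0, P3 against P0, P6 against P3 and P10 against P6 within each population, and the interaction. The interaction is the difference between crypt and villus in the change from P0 to P10. Log2 CPM values used a prior count of 2. A gene called at all 4 ages in the same direction between crypt and villus was counted as shared. Where a group held no counts of a gene, its fold was bounded against a floor of 3 counts over the group. Where it held up to 3, a ratio with its 95% exact interval was given.

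A set of 32 gene lists was tested with camera from limma 3.58.1 on voom values of the same genes, with an inter-gene correlation of 0.01 and adjustment over the lists within a contrast. Results are given for 31 of them. Each was also counted by its members past the threshold, over all genes and adjusted over the list alone. The tests, the alternatives, the lists and the rule for naming genes were fixed before the data were examined.

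Outside the lists, the rule named genes past the threshold with a mean log2 CPM of at least 3. Between crypt and villus it took the 10 highest and 10 lowest mean differences among shared genes and the 5 largest per direction at a single age. From P0 to P10 it took the 10 largest per direction among genes whose groups did not overlap, between adjacent ages 4, and for the interaction 8. From each list it took the 4 largest called members and up to 2 uncalled ones, of which part are printed. A fixed set of 24 sort, cell type, enterocyte, adhesion and growth genes was named whatever its values.

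Set beforehand as other ways of processing were scaling by DESeq2's size factors or by library size alone, no filter or a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, fits of only the groups compared, counts thinned to the smallest total, the replicate number as a block, and each library left out in turn. For lists they were camera with an estimated correlation and fry, not the block within age. Chosen after seeing the data were offsets for a smooth trend on GC content and length (splines with 5 degrees of freedom), alone or with the block, and fits without mitochondrially encoded genes, without both P0 replicate 1 libraries, or without the P3 and P6 libraries.

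Whether equal replicate numbers pair crypt and villus libraries of an age was checked from the correlation over genes of their deviations from the group means, as the labels state no pairing. At P3 same-numbered libraries had correlations of 0.408, 0.637 and 0.273, and at P10 of 0.635, 0.557 and 0.581. From the data alone these ages were treated as paired, and fitted also with a replicate block within age.

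The pipeline was tested on simulated counts for 15826 genes with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. For crypt at P10 against P0, 11.9%, 70.1% and 95.5% of them were recovered, and for crypt against villus at P10 5.97%, 70.1% and 95.5%. With the 2 libraries of P6 villus, over 15833 genes, 1.49%, 38.8% and 93.9% were recovered for crypt against villus.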

Results

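Gene counts were compared in epithelial cells of the medial small intestine of CD1 mice, an outbred stock, at postnatal days 0, 3, 6 and 10 (P0, P3, P6 and P10). Epcam-positive cells were sorted into a CD44-positive population, called crypt here, and a CD44-negative one, called villus. The 23 libraries fell into 8 groups of 3, except that P6 villus had 2. Library totals ranged from 23545159 to 37055554 counts, and 18325 to 22099 genes had at least a count in a library. The design asks how the populations differ at each age, how each changes with age, and whether that change differs. Fold changes are log2 values, with standard errors after ± from the model fitted over all 23 libraries. Adjusted p-values (Benjamini-Hochberg) are from edgeR's quasi-likelihood test for genes and camera for gene lists. The labels do not say that replicates came from separate animals, so p-values measure the spread between these libraries.

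The P3 and P6 libraries lay apart from the P0 and P10 libraries along principal component 1, which held 58.4% of the variance of log2 CPM (counts scaled to library size). Over genes, which are not independent replicates, the loading on this component had a Spearman correlation of -0.816 with transcript GC content. The mean GC content of the counted transcripts was 49.99% ± 0.347 (SD, n = 3) in P0 crypt and 50.07% ± 0.139 in P0 villus. It was 47.13% ± 0.689 and 47.12% ± 0.569 at P3, 45.48% ± 0.171 (n = 3) and 45.48% ± 0.177 (n = 2) at P6, and 49.87% ± 0.131 and 50.27% ± 0.0551 at P10. P0 and P10 are thus compared first, and adjacent ages last.

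**Figure D1:**
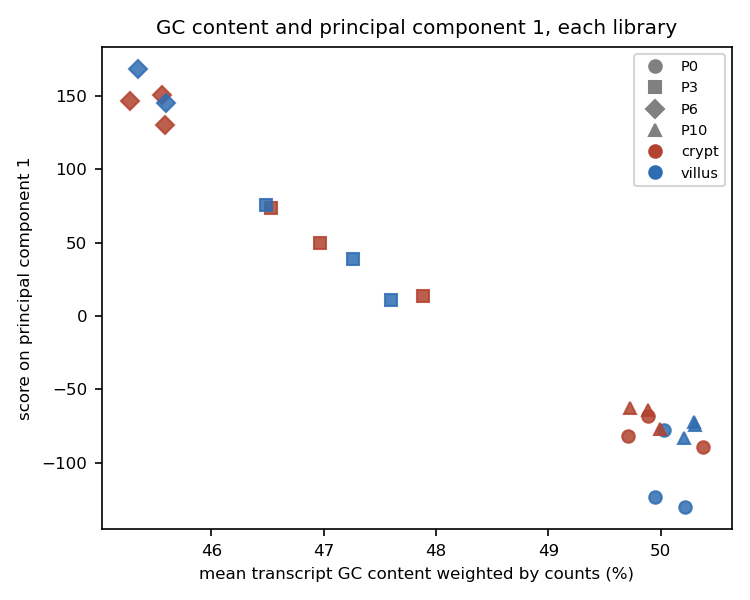
Each point is a library; the axes give the mean transcript GC content of its counts (percent) and its score on principal component 1 (no unit), for crypt and villus cells at 4 ages. P3 and P6 libraries have lower GC content and positive scores, P0 and P10 libraries higher GC content and negative scores.

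Cd44, the gene of the sorted surface protein, was higher in crypt by 2.69 ± 0.38 at P0 (adjusted p = 4.22e-05) and 1.60 ± 0.35 at P10 (adjusted p = 0.00263). As the sort used its product, this only checks the labels. Its CPM was 42.8 ± 10.8 (SD, n = 3) in P0 crypt and 6.55 ± 4.01 in P0 villus. Epcam, the other sort gene, was higher in crypt at P0 (0.65 ± 0.14, adjusted p = 0.00267) and did not pass at P10 (0.29 ± 0.14, adjusted p = 0.15).

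**Figure D2:**
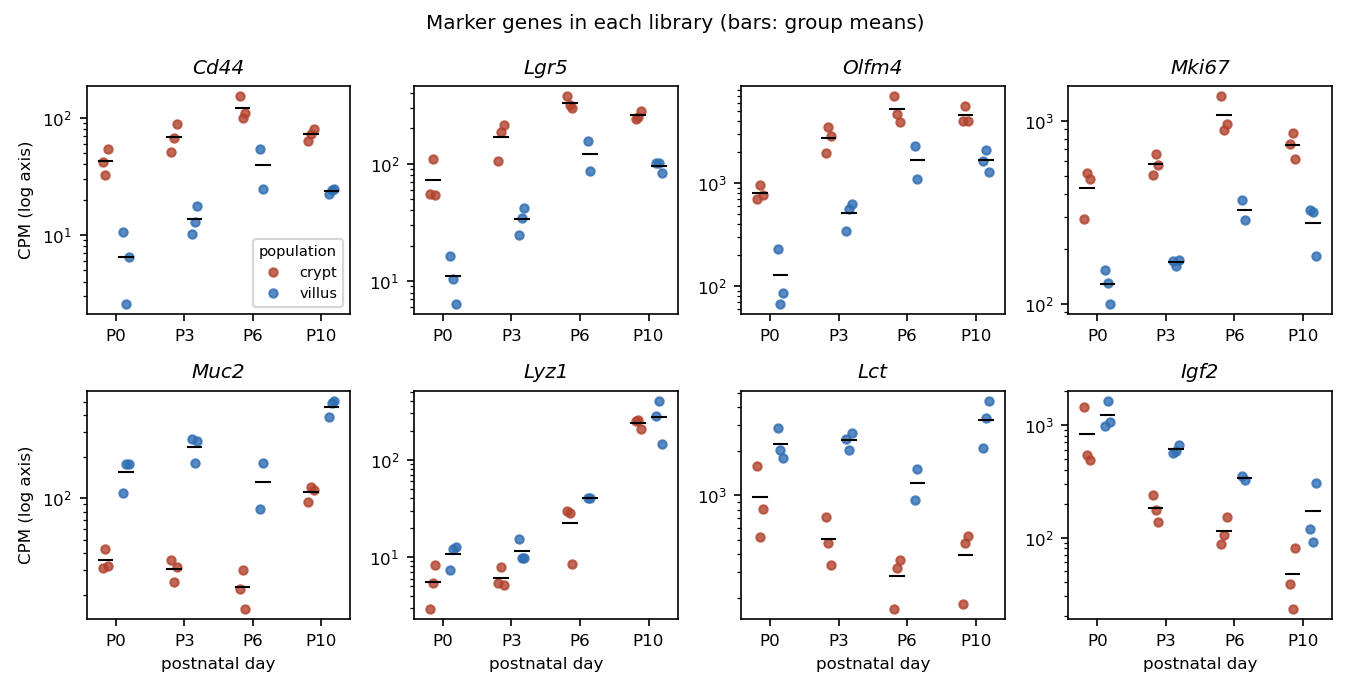
CPM on a log axis for marker genes in crypt and villus libraries at P0, P3, P6 and P10; points are libraries and bars are group means. Olfm4 lies higher in crypt and rises with age, while Lyz1 is low until P6 in both populations and high at P10.

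Crypt cells differed from villus cells in proliferation and stem cell genes at every age. The hormone gene Gip had the highest mean difference over the 4 ages (mean log2 3.81), followed by the mitotic genes Kif18b (2.15) and Plk1 (2.11), then Cd44 (2.06) and the spindle gene Aspm (2.05). Next came the stem cell gene Olfm4 (2.04), Kif14 (2.03), the cytokinesis gene Anln (2.03), Clca3b (2.02) and Pcdh8 (2.02). Of 16535 genes tested, 1765 were called in the same direction at all 4 ages, 1110 of them higher in crypt and 655 higher in villus. Independent lists of these sizes would share 6.03 and 3.56. Another 5 genes were called in opposite directions at different ages. The shared count was 770 without P6 villus 2, where the P6 calls of Cd44, Olfm4 and Pcdh8 were lost (log2 1.26, 1.28 and 0.92). Without P6 crypt 1, Olfm4 and Pcdh8 lost theirs as well (1.35 and 1.23). Fitting only the groups compared gave 636 shared calls.

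All 43 tested members of the cell cycle list were higher in crypt at P0 and P3, 41 at P6 and 42 at P10, and all 43 passed at each age when adjusted over the list alone. The list medians were 1.75, 1.80, 1.62 and 1.35. Kif11, a mitotic motor, differed by 2.53 ± 0.29 at P0 and 1.63 ± 0.28 at P10, and the proliferation gene Mki67 by 1.75 ± 0.25 and 1.42 ± 0.25. Of 24 intestinal stem cell genes, 21, 21, 16 and 20 were higher at P0, P3, P6 and P10 (21, 21, 20 and 23 adjusted over the list alone), with none lower. Lgr5, a Wnt receptor component of stem cells, differed by 2.70 ± 0.35 at P0 and 1.43 ± 0.33 at P10, Olfm4 by 2.65 ± 0.41 and 1.44 ± 0.39, and the transcription factor gene Ascl2 by 1.73 ± 0.32 and 1.38 ± 0.31. The P10 call of Olfm4 was lost without P10 villus 3 (1.28). Camera gave p of at most 8.07e-32 for cell cycle and 1.36e-10 for stem cell genes. These became adjusted p = 0.0795 to 0.143 and adjusted p = 0.143 to 0.263 with an estimated correlation.

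Ribosome biogenesis genes were also higher in crypt, 17, 25, 25 and 19 of 26 at P0, P3, P6 and P10 (22, 26, 26 and 25 adjusted over the list alone). The examples are Utp20 at P0 (1.53 ± 0.25) and Nop56 at P10 (1.06 ± 0.21). The camera p was at most 1.06e-08 (adjusted p = 0.195 to 0.407 with an estimated correlation). Of 22 Wnt target genes, 15, 14, 11 and 13 were higher and 0, 2, 2 and 1 lower (16, 15, 13 and 17 higher and 1, 3, 3 and 3 lower adjusted over the list alone). Axin2, a feedback gene of the pathway, differed by 1.92 ± 0.28 at P0. Notum, which codes for an enzyme that inactivates Wnt proteins, was lower in crypt at P10 (-1.98 ± 0.55), a call lost without P10 crypt 1 (-1.66) or P10 villus 3 (-1.76). The Wnt list had camera p of at most 0.00049 (adjusted p = 0.143 to 0.264 with an estimated correlation).

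Goblet and absorptive genes were higher in villus. Zg16, which codes for a goblet cell lectin, had the largest mean difference (mean log2 -4.01), followed by the neuropeptide gene Nts (-3.24), the goblet cell gene Clca1 (-2.82), Smcp (-2.71) and Paqr9 (-2.54). Next came Dnah2 (-2.50), Syne1 (-2.50), Gm2061 (-2.49), Fabp1 (-2.48), which codes for a fatty acid binding protein, and Gm9765 (-2.47). Without P6 villus 2, the P6 calls of Paqr9, Dnah2, Syne1 and Fabp1 were lost (-1.74, -1.45, -2.16 and -1.50), and Dnah2 lost its P6 call without P6 crypt 1 (-1.78). Without P0 villus 2, Smcp and Gm2061 lost their P0 calls (-1.44 and -1.29). Gm2061 also lost its own without P0 crypt 3 (-1.54), and Paqr9 without P0 crypt 2, P0 crypt 3, P0 villus 1 or P0 villus 3 (-1.33, -1.60, -1.44 and -1.71).

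Of 32 mature enterocyte genes, 9, 28, 24 and 27 were lower in crypt at P0, P3, P6 and P10 (11, 29, 26 and 28 adjusted over the list alone), with 1 higher at each age. Fabp1 differed by -1.99 ± 0.44 at P0 and -3.42 ± 0.47 at P10, and Rbp2, a retinol binding protein gene, by -3.39 ± 0.46 at P10. Vil1, which codes for the microvillus protein villin, did not pass at P0 (-0.30 ± 0.18, adjusted p = 0.22) and was lower in crypt at P10 (-0.84 ± 0.18). The alkaline phosphatase gene Alpi had -0.85 ± 0.39 (adjusted p = 0.109) at P0 and -2.56 ± 0.41 at P10. At P0 it passed without P0 crypt 1 (-1.50). By camera, p for the list was at most 4.98e-06 (adjusted p = 0.143 to 0.513 with an estimated correlation). Of 23 lipid absorption genes, 12, 22, 20 and 22 were lower in crypt (16, 22, 23 and 22 adjusted over the list alone) and none higher. Apoc2, an apolipoprotein gene, had -3.34 ± 0.64 at P10. The list's camera p was at most 8.8e-08 (adjusted p = 0.143 to 0.513 with an estimated correlation). Mature enterocyte and lipid absorption genes overlap in part. Of 28 lysosome genes, 4, 23, 16 and 20 were lower in crypt (2, 26, 21 and 22 adjusted over the list alone), including Lipa (-2.44 ± 0.49) and Neu1 (-2.29 ± 0.37) at P10. Camera gave p of at most 0.000661 (adjusted p = 0.225 to 0.585 with an estimated correlation).

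Of 13 suckling-type enterocyte genes, 3, 11, 7 and 9 were lower in crypt (3, 11, 9 and 11 adjusted over the list alone), and 1, 1, 0 and 0 higher (1, 1, 0 and 1 adjusted over the list alone). The lactase gene Lct had -1.19 ± 0.42 at P0 and -3.06 ± 0.45 at P10. Its P0 call was lost without P0 crypt 2, P0 crypt 3, P0 villus 1, P0 villus 2 or P0 villus 3 (-0.89, -1.07, -0.97, -1.26 and -1.33). Fcgrt, the gene of the neonatal IgG receptor, had -1.31 ± 0.54 (adjusted p = 0.0779) and -2.84 ± 0.57. It passed at P0 without P0 crypt 1 (-2.45). Ass1, a urea cycle enzyme gene, had -1.13 ± 0.57 (adjusted p = 0.149) and -2.82 ± 0.61. Prdm1, a repressor of the adult enterocyte programme, had 0.25 ± 0.19 (adjusted p = 0.335) and -0.76 ± 0.19, and passed at P0 without P0 villus 1 (0.48). The list had camera adjusted p = 0.0304, 1.51e-05, 4.53e-05 and 4.33e-07 at the 4 ages (adjusted p = 0.143 to 0.585 with an estimated correlation). The P0 call was lost without P0 crypt 2 (adjusted p = 0.0654), P0 crypt 3 (0.0694), P0 villus 1 (0.168) or P0 villus 2 (0.0728).

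Of 19 genes of fatty acid oxidation and ketogenesis, 2, 7, 3 and 10 were lower in crypt (2, 8, 3 and 11 adjusted over the list alone). The list had camera adjusted p = 0.0388 at P0 and at most 0.00112 later (adjusted p = 0.284 to 0.639 with an estimated correlation). Its P0 call was lost without P0 crypt 2 (0.665), P0 villus 1 (0.536) or P0 villus 3 (0.105). Adult-type enterocyte genes did not pass at any age (camera adjusted p = 0.0736 to 0.195): 2, 4, 2 and 2 of 9 were lower (2, 4, 2 and 3 adjusted over the list alone) and 1 higher at P0 alone. Sis, the sucrase-isomaltase gene, had 0.18 ± 0.41 at P0 (adjusted p = 0.776) and -0.69 ± 0.41 at P10 (adjusted p = 0.24). With replicate numbers as a block within age this list passed at P3 (adjusted p = 0.0419) and P10 (0.0407), and at P10 also without P10 crypt 1 (0.0497) or P10 villus 3 (0.0434).

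**Figure D3:**
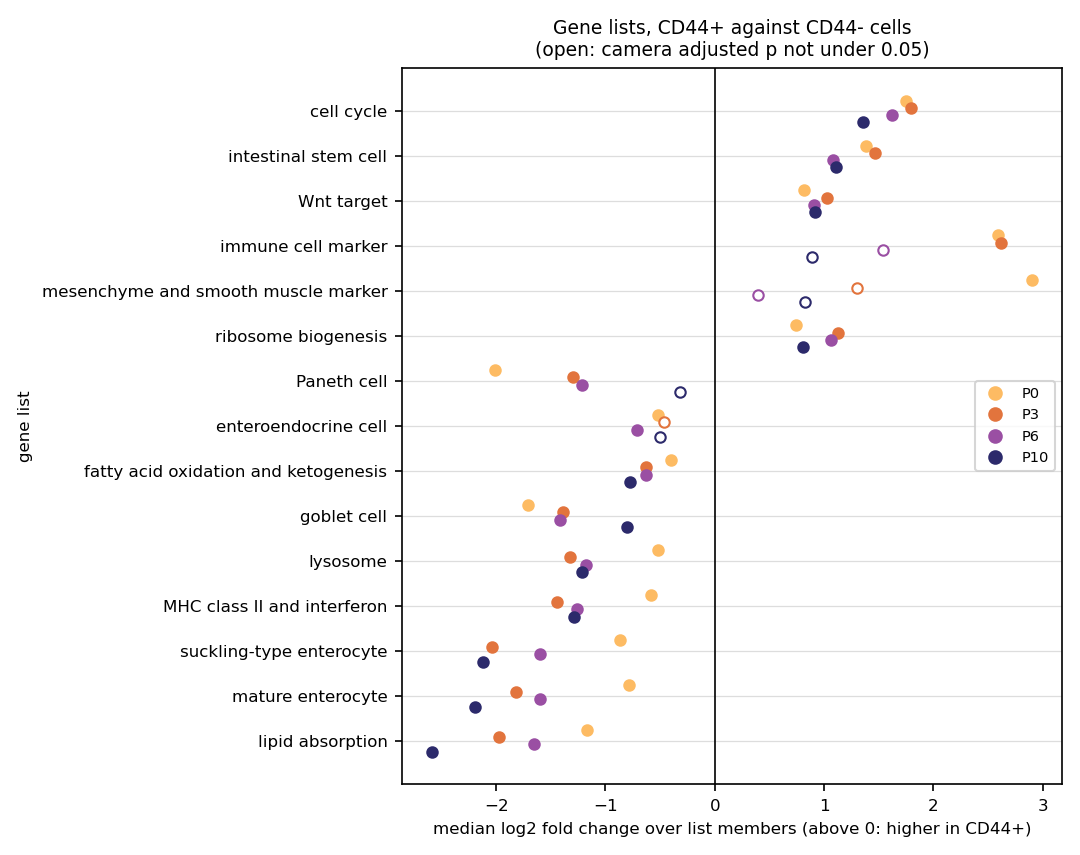
Median log2 fold change of crypt against villus for each gene list past the threshold at any of P0, P3, P6 and P10. Cell cycle genes have medians of 1.75, 1.80, 1.62 and 1.35, and lipid absorption genes of -1.17, -1.98, -1.65 and -2.59.

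Many goblet cell genes were higher in the CD44-negative cells at each age, and part of the Paneth cell genes. Of 21 goblet cell genes, 14, 12, 11 and 9 were lower in crypt at P0, P3, P6 and P10 (15, 13, 15 and 11 adjusted over the list alone), with 1 higher at P0. Muc2, the main intestinal mucin gene, had -2.11 ± 0.28 at P0 and -2.06 ± 0.28 at P10, and the trefoil factor gene Tff3 had -2.74 ± 0.41 at P0. The camera p was at most 1.03e-05 (adjusted p = 0.234 to 0.407 with an estimated correlation). Of 19 Paneth cell genes, 10, 10, 4 and 1 were lower in crypt (14, 10, 4 and 1 adjusted over the list alone) with list medians of -2.01, -1.30, -1.21 and -0.32, and 1 was higher at P0. Itln1, which codes for an intelectin, had -2.14 ± 0.34 at P10. The lysozyme gene Lyz1 had -0.95 ± 0.42 (adjusted p = 0.101) at P0 and -0.20 ± 0.40 (adjusted p = 0.762) at P10, and the matrilysin gene Mmp7 -1.15 ± 0.61 (adjusted p = 0.166) and -0.16 ± 0.57 (adjusted p = 0.869). The Paneth list had camera adjusted p = 0.000262, 0.00726 and 0.000204 at P0, P3 and P6 (adjusted p = 0.369 to 0.537 with an estimated correlation). At P10 it had 0.177, but 0.0429 with the replicate block within age and 0.00813 without P10 villus 3. Counts of single defensin and Clca genes are uncertain because near-identical copies can share reads.

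Of 26 enteroendocrine genes, 11, 4, 6 and 5 were lower and 2, 2, 1 and 1 higher in crypt (12, 4, 6 and 5 lower and 2, 2, 1 and 1 higher adjusted over the list alone). Gip, the K cell hormone gene, had 3.43 ± 0.64 at P0 and 3.80 ± 0.65 at P10, whereas Nts had -3.79 ± 0.64 and -2.27 ± 0.60. The granule protein gene Chga had -2.45 ± 0.46 and -1.66 ± 0.45, the latter call lost without P10 crypt 2 (-1.46). The list passed as lower in crypt at P0 (adjusted p = 0.00118) and P6 (0.00251), with adjusted p = 0.585 and adjusted p = 0.724 with an estimated correlation. It had 0.51 at P3 and 0.232 at P10, where it passed without P10 crypt 1 (0.0211). Tuft cell genes did not pass (camera adjusted p = 0.543 to 0.745): 2, 2, 0 and 1 of 11 were higher and 1, 3, 2 and 3 lower (2, 2, 2 and 1 higher and 1, 3, 3 and 3 lower adjusted over the list alone). The tuft marker Dclk1 had 5 counts over the P0 crypt and 3 over the P0 villus libraries, a ratio of 1.34 (95% counting interval 0.261 to 8.64), and a log2 difference of -1.02 ± 0.60 (adjusted p = 0.234) at P10. Pou2f3, the tuft cell transcription factor gene, was higher in crypt at P10 (1.96 ± 0.43).

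Of 22 genes of MHC class II and interferon response, 4, 16, 12 and 13 were lower in crypt and 3, 2, 0 and 0 higher (5, 16, 13 and 13 lower and 3, 3, 0 and 1 higher adjusted over the list alone). The interferon-induced gene Ifit1 had -3.14 ± 0.43 at P10. Cd74 and H2-Aa, which act in antigen presentation, were higher in crypt at P0 (2.78 ± 0.67 and 3.91 ± 0.98), calls lost without P0 crypt 1 (1.57 and 2.35). The list had camera adjusted p = 0.0129, 1.14e-05, 6.95e-05 and 4.51e-05 (adjusted p = 0.284 to 0.585 with an estimated correlation). The P0 call was lost without P0 crypt 2 (0.201) or P0 villus 1 (0.0894). Antimicrobial genes did not pass at any age (camera adjusted p = 0.173 to 0.745), with 2, 0, 0 and 0 of 14 higher and 2, 3, 3 and 3 lower, the same counts adjusted over the list alone. At P6 the list passed without P6 crypt 2 (0.0135) or P6 villus 1 (0.00873).

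Markers of cells outside the epithelium also differed between the sorted populations. Of 14 immune cell markers, 8 at P0 and 10 at P3 were higher in crypt, with 0, 1, 1 and 1 lower over the 4 ages (8 and 10 higher and 1, 1, 0 and 1 lower adjusted over the list alone), none higher at P6 or P10. Ptprc, which codes for the leukocyte protein CD45, had 53 counts over the P0 crypt and 1 over the P0 villus libraries, a ratio of 42.7 (95% counting interval 7.34 to 1720). The list had camera adjusted p = 0.00425 at P0 and 0.00177 at P3 (adjusted p = 0.493 and adjusted p = 0.256 with an estimated correlation), and a P0 median of 2.59, or 2.27 with members at 0 set to their bound. The P0 call was lost without P0 villus 1 (0.0919). Of 16 mesenchyme and smooth muscle markers, 10 were higher in crypt at P0 (12 adjusted over the list alone) and none passed at P3, P6 or P10. Col3a1, a fibroblast collagen gene, had 4.62 ± 1.04 at P0. The list had camera adjusted p = 0.0332 (adjusted p = 0.625 with an estimated correlation), lost without P0 crypt 1 (0.283) or P0 villus 1 (0.308), and a P0 median of 2.90, or 2.74 with a member at 0 set to its bound.

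Integrin, laminin and myosin genes bear on how cells hold to the basement membrane, a question of the study. Itga6, the integrin alpha 6 gene of hemidesmosomes, was higher in crypt at P0 (1.33 ± 0.28) and P10 (1.06 ± 0.27), while its partner Itgb4 did not pass (-0.30 ± 0.26, adjusted p = 0.407, and -0.33 ± 0.26, adjusted p = 0.401). At P10 the collagen gene Col4a2 (-2.75 ± 0.63), the laminin gene Lama3 (-2.74 ± 0.40) and the linker gene Dst (-1.85 ± 0.23) were lower in crypt. Over this hemidesmosome and basement membrane list, 6, 4, 2 and 5 of 23 were higher and 2, 7, 4 and 5 lower at P0, P3, P6 and P10 (6, 5, 2 and 5 and 2, 7, 4 and 5 adjusted over the list alone), with camera adjusted p = 0.464 to 0.586. Rac1, a small GTPase gene, had 0.03 ± 0.11 (adjusted p = 0.882) at P0 and 0.05 ± 0.11 (adjusted p = 0.794) at P10. Myh9, the gene of nonmuscle myosin heavy chain IIA, was higher in crypt by 0.80 ± 0.20 and 0.65 ± 0.20, the P10 call lost without P10 crypt 2, P10 villus 1 or P10 villus 3 (0.56, 0.63 and 0.58). Of 26 cell junction genes, 6, 1, 0 and 1 were higher and 0, 4, 0 and 2 lower (7, 0, 0 and 0 and 1, 0, 0 and 0 adjusted over the list alone), with camera adjusted p = 0.0717 at P0 and 0.449 to 0.908 later. At P0 it passed without P0 villus 1 (0.0031).

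Other lists did not pass at any age between crypt and villus. Notch pathway genes (camera adjusted p = 0.183 to 0.586) had 3, 3, 2 and 3 of 17 higher and 0, 2, 1 and 0 lower (3, 3, 2 and 3 and 0, 1, 1 and 0 adjusted over the list alone), among them the receptor gene Notch1 (1.60 ± 0.25 at P0, 1.19 ± 0.24 at P10). BMP and hedgehog genes (camera adjusted p = 0.47 to 0.945) had 3, 3, 2 and 1 of 16 higher and 1, 3, 3 and 1 lower, with 1, 3, 4 and 1 lower adjusted over the list alone. Fetal and Yap-associated genes (camera adjusted p = 0.565 to 0.78) had 2, 2, 2 and 1 of 16 higher and 1, 4, 3 and 3 lower, the same counts adjusted over the list alone. Imprinted and oncofetal growth genes (camera adjusted p = 0.355 to 0.908) had 5, 4, 3 and 5 of 19 higher and 1, 6, 4 and 6 lower (5, 5, 4 and 5 and 1, 6, 5 and 6 adjusted over the list alone). Among these, Igf2, a fetal growth factor gene, had -0.56 ± 0.46 (adjusted p = 0.382) at P0 and -1.85 ± 0.47 at P10, and the noncoding gene H19 had -1.36 ± 0.70 (adjusted p = 0.159) and -2.39 ± 0.73. The P10 call of Igf2 was lost without P10 villus 3 (-1.16), and that of H19 without P10 crypt 1, P10 crypt 2 or P10 villus 3 (-2.18, -1.96 and -1.09).

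Circadian clock genes (camera adjusted p = 0.414 to 0.745) had 1, 2, 0 and 0 of 13 higher and 2, 4, 2 and 1 lower. Ileal genes (camera adjusted p = 0.138 to 0.336) had 2 of 6 lower at each age, Slc51b, a bile acid transporter gene, by -2.48 ± 0.37 at P10. Dissociation stress genes (camera adjusted p = 0.464 to 0.573) had 0, 1, 0 and 0 of 14 higher. Endothelial markers (camera adjusted p = 0.247 to 0.772) had 1, 0, 0 and 1 of 3 lower. Enteric neuron and glia markers (camera adjusted p = 0.141 to 0.713) had 1 of 7 higher at P0 and 3, 2, 2 and 2 lower, and passed at P10 without P10 crypt 1 (0.0481). Erythroid markers (camera adjusted p = 0.471 to 0.886) had 1 of 3 higher at each age and 1 lower at P10. Pancreatic acinar markers (camera adjusted p = 0.313 to 0.673) had 1, 2, 2 and 2 of 8 lower. Adjusted over the list alone these counts were the same, except 3 higher at P3 for the clock and 0 at P3 for the stress genes.

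The counts of genes past the threshold between crypt and villus were 4427 at P0 (2731 higher in crypt), 5482 at P3 (2707), 3544 at P6 (1766) and 4011 at P10 (2089). The higher share was 61.7%, 49.4%, 49.8% and 52.1%. With library sizes alone as scaling it was 80.8%, 76.8%, 70.3% and 70.1%, as the median of all genes moved to 0.21, 0.37, 0.26 and 0.27. At P0 the largest differences per direction included Gip, Pcdh8 (2.77 ± 0.39), Lgr5, Cd44 and Clca3b (2.67 ± 0.26), and Nts, Zg16 (-3.47 ± 0.62), Ffar2 (-2.86 ± 0.40) and Tff3. At P3 they added Iqgap3 (2.36 ± 0.32), St3gal5 (-3.11 ± 0.68) and Susd2 (-3.00 ± 0.77). At P10 they added Rgs4 (1.83 ± 0.44), Prr11 (1.67 ± 0.25), Kif14 (1.64 ± 0.26) and Slc6a3 (-3.33 ± 0.47). At P6 the heads were Hspg2, Gip (3.90 ± 0.81), Evpl, Pkmyt1 (2.66 ± 0.76) and Eme1 (2.39 ± 0.36), and Zg16, Clca1, Nts, Itln1 (-2.89 ± 0.37) and Fam198b (-2.85 ± 0.61). Hspg2 and Evpl had 2 counts each over the P6 villus libraries, for ratios of 16.4 (95% counting interval 4.35 to 138) and 9.24 (2.37 to 79.3). Without P6 villus 2, the calls of Hspg2, Evpl, Pkmyt1 and Fam198b were lost (4.08, 3.26, 3.39 and -2.26). Without P6 villus 1, those of Hspg2, Evpl and Pkmyt1 were lost (3.96, 3.14 and 2.31), and Hspg2 lost its own without P6 crypt 3 (3.35).

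The count at P0 fell to 2421 without P0 crypt 3, 2845 without P0 villus 2 and 2777 without P0 villus 3, and to 798 when only the 6 libraries compared were fitted. At P6 it was 2304 without P6 crypt 1 and 1223 without P6 villus 2. At P10 it was 2304 without P10 villus 3, 6085 when only the 6 libraries were fitted, and 6362 with GC content and length offsets and the replicate block within age.

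Between P0 and P10, Paneth cell genes rose and fetal growth genes fell in the crypt cells. Lyz1 rose by 5.43 ± 0.49 (adjusted p = 8.87e-07), from 5.54 ± 2.69 CPM (SD, n = 3) to 239 ± 27.1. Pla2g2a, a secreted phospholipase gene, went from 0 counts over the P0 libraries to 3771 at P10, at least 1220-fold higher against a floor of 3 counts over the group, with 148 to 3432 counts per library, so that 1 library held most of them. Its call was lost with limma-voom and when only the groups compared were fitted. Gm15284 (5.45 ± 0.61), Defa17 (3.62 ± 0.48), the ribonuclease gene Ang4 (3.59 ± 0.68), A2m (3.10 ± 0.39), Mmp7 (3.07 ± 0.63), 2210407C18Rik (2.96 ± 0.47) and Defa24 (2.91 ± 0.35) were also among the 10 largest rises, taken over genes with a mean log2 CPM of at least 3 whose groups did not overlap. The 10 largest falls by the same rule were the desaturase gene Scd2 (-6.35 ± 1.51), the bile salt transporter gene Abcb11 (-6.19 ± 1.40), Ggt1 (-5.98 ± 0.78), H19 (-5.66 ± 0.85), Upk3b (-5.17 ± 0.91), Alpk3 (-5.17 ± 0.93), Igf2os (-4.68 ± 0.58), the alpha-fetoprotein gene Afp (-4.51 ± 0.79), Igf2 (-4.12 ± 0.52) and the fatty acid receptor gene Cd36 (-4.08 ± 0.77). Igf2os overlaps Igf2 on the other strand and the strand setting of the counting is not given in the sources used here, so their reads cannot be told apart.

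Of 19 Paneth cell genes, 16 rose in crypt cells and none fell, the same counts adjusted over the list alone, with a median of 3.59, the same with Pla2g2a at its bound (camera adjusted p = 2.64e-15; adjusted p = 0.046 with an estimated correlation). Of 22 Wnt targets, 16 rose (17 adjusted over the list alone), including Axin2 (2.18 ± 0.28) and Sp5 (3.28 ± 0.53), with camera adjusted p = 1.41e-13 (adjusted p = 0.00799 with an estimated correlation). Of 19 imprinted and oncofetal genes, 12 fell and 1 rose (15 and 1 adjusted over the list alone), with camera adjusted p = 4.5e-07 (adjusted p = 0.00799 with an estimated correlation). Of 24 stem cell genes, 16 rose (19 rose and 1 fell adjusted over the list alone), including Tnfrsf19 (4.57 ± 0.58), Gkn3 (3.70 ± 0.68), Olfm4 (2.50 ± 0.41), Lgr5 (1.82 ± 0.33) and Ascl2 (1.41 ± 0.31), with camera adjusted p = 2.64e-14 (adjusted p = 0.0726 with an estimated correlation). Of 21 goblet genes, 7 rose (11 adjusted over the list alone), among them Spink4 (1.95 ± 0.43) and Muc2 (1.63 ± 0.28), with camera adjusted p = 3.44e-06 (adjusted p = 0.274 with an estimated correlation). Notch genes rose in 3 of 17 (3 adjusted over the list alone), among them the secretory fate gene Atoh1 (1.49 ± 0.35), with camera adjusted p = 0.00234 (adjusted p = 0.274 with an estimated correlation). Antimicrobial genes rose in 5 and fell in 1 of 14 (7 and 1 adjusted over the list alone), among them Lcn2 (4.68 ± 0.95) and the immunoglobulin transporter gene Pigr (1.66 ± 0.29), with camera adjusted p = 0.00265 (adjusted p = 0.274 with an estimated correlation).

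Enterocyte genes fell in the CD44-positive cells over the same days. Of 32 mature enterocyte genes 20 fell (22 adjusted over the list alone), led by Ggt1, Fabp1 (-3.24 ± 0.46) and Rbp2 (-3.23 ± 0.46), and Alpi fell by 1.92 on the log2 scale, while Vil1 had -0.30 ± 0.18 (adjusted p = 0.277). Of 23 lipid absorption genes 18 fell and 1, Pnliprp2, a pancreatic lipase-related gene (2.98 ± 0.35), rose (20 and 1 adjusted over the list alone). Of 28 lysosome genes 11 fell (17 adjusted over the list alone), of 19 genes of fatty acid oxidation 8 (15), and of 13 suckling-type genes 6 (7). Ass1 had -3.40 ± 0.63 and Lct -1.31 ± 0.42, while Fcgrt (-1.51 ± 0.54, adjusted p = 0.0617), Prdm1 (-0.13 ± 0.19, adjusted p = 0.685) and Sis (0.24 ± 0.41, adjusted p = 0.726) did not pass. The call of Lct was lost without P0 crypt 1, P10 crypt 1 or P10 crypt 2 (-0.76, -0.96 and -1.46), and Fcgrt passed without P0 crypt 2 or P0 crypt 3 (-1.94 and -1.78) or with GC and length offsets (-1.40). By camera, p was at most 0.000427 for these 5 lists (adjusted p = 0.274 to 0.444 with an estimated correlation). The P0 baseline varied, with mature enterocyte medians of 1.27 in P0 crypt 1 and -1.01 in P0 crypt 2 against the other P0 crypt libraries.

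In crypt cells Itga6 rose by 0.89 ± 0.27 and Myh9 by 0.61 ± 0.20, Rac1 fell by 0.33 on the log2 scale (SE 0.11), and Itgb4 had 0.10 ± 0.26 (adjusted p = 0.833). The calls of Rac1 and Myh9 were lost when any of the 6 libraries compared was left out (Rac1 -0.31 to -0.35, Myh9 0.47 to 0.68), that of Rac1 with library sizes alone as scaling (-0.14), and that of Itga6 without P0 crypt 1, P0 crypt 2 or any P10 crypt library (0.80 to 0.96). Of 23 hemidesmosome and basement membrane genes, 6 rose, such as Itga1 (2.25 ± 0.41), and 4 fell, such as Col4a1 (-4.15 ± 0.84) and Lama1 (-3.48 ± 0.62), or 8 and 6 adjusted over the list alone (camera adjusted p = 0.281, and 0.0311 without both P0 replicate 1 libraries). Cell cycle genes rose in 2 and fell in 3 of 43 (0 and 0 adjusted over the list alone; camera adjusted p = 0.675). Mki67 had 0.78 ± 0.25, a call lost without P0 crypt 1, P10 crypt 1 or P10 crypt 2 (0.56, 0.77 and 0.66) or with GC and length offsets (0.60). Ribosome biogenesis, enteroendocrine, dissociation stress, MHC class II, immune and mesenchyme lists had camera adjusted p = 0.0678, 0.12, 0.115, 0.339, 0.362 and 0.0744. Without P0 crypt 1, the enteroendocrine and stress lists passed (0.000144 and 0.00242). Without P0 crypt 2, ribosome biogenesis, MHC class II, immune and mesenchyme passed (0.00869, 0.0309, 0.0412 and 0.000178). Ribosome biogenesis also passed without P0 crypt 3 (0.0151) or P10 crypt 3 (0.0167), enteroendocrine without P10 crypt 2 (0.00305), stress without P10 crypt 1 (0.0203), and mesenchyme without P10 crypt 1 (0.0102) or P10 crypt 3 (0.0481). Markers of other cells had negative medians as well, mesenchyme -1.59, 3 endothelial genes -1.26 and pancreatic -3.50 (-3.03 with members at 0 set to their bound). Chga (0.76 ± 0.44, adjusted p = 0.262), Dclk1 (0.92 ± 0.71, adjusted p = 0.408) and Epcam (0.16 ± 0.14, adjusted p = 0.482) did not pass.

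In total 2829 genes differed between P10 and P0 crypt cells, 1194 (42.2%) higher and 1635 lower at P10. Library sizes alone as scaling gave 67.9% higher, with the median of all genes at 0.17. GC and length offsets gave 3840 calls, 36.5% of them higher. The count was 1454 without P0 crypt 1, 1512 without P10 crypt 1, 1701 without P10 crypt 2 and 1863 without P10 crypt 3.

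In villus cells Paneth and stem cell genes rose as well between P0 and P10, and fetal growth genes fell. Pla2g2a went from 3 counts over the P0 libraries to 4386 at P10, a ratio of 1170 (95% counting interval 402 to 5700), with 129 to 3888 counts per library, and its call was lost with limma-voom. Lyz1 rose by 4.68 ± 0.47, Pcdh8 by 4.07 ± 0.40, 2210407C18Rik by 3.86 ± 0.51, the monocarboxylate transporter gene Slc5a8 by 3.77 ± 0.39, Olfm4 by 3.71 ± 0.43 and A2m by 3.62 ± 0.41. Reg3b (4.25 ± 1.31) and Reg3g (4.19 ± 1.22), lectin genes alike in sequence, were also among the 10 largest rises by the crypt rule. The call of Reg3b was lost without any of the P0 villus libraries, P10 villus 1 or P10 villus 2 (3.73 to 4.78), and that of Reg3g without P0 villus 1, P0 villus 2 or P10 villus 1 (4.06, 3.86 and 3.67). The 10 largest falls by the same rule were Scd2 (-5.45 ± 1.45), Ggt1 (-4.96 ± 0.72), Abcb11 (-4.72 ± 1.20), Alpk3 (-4.67 ± 0.88), H19 (-4.62 ± 0.81), the ghrelin gene Ghrl (-4.16 ± 0.87), Upk3b (-4.07 ± 0.84), H2-Q10 (-3.41 ± 0.42), Igf2os (-3.28 ± 0.53) and Lgals3 (-3.11 ± 0.59). Igf2 had -2.83 ± 0.49. The calls of Scd2 and Abcb11 were lost without P0 villus 2 (-1.77 and -2.38) or P10 villus 2 (-4.97 and -4.50).

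Of 24 stem cell genes, 19 rose in villus cells (20 adjusted over the list alone), including Tnfrsf19 (5.59 ± 0.73), Lgr5 (3.10 ± 0.35) and Ascl2 (1.75 ± 0.32), with camera adjusted p = 1.76e-14 (adjusted p = 0.0863 with an estimated correlation). Paneth genes rose in 15 of 19 (15 adjusted over the list alone; median 2.09; camera adjusted p = 1.54e-10; adjusted p = 0.128 with an estimated correlation). Mmp7 had 2.08 ± 0.60, a call lost without P0 villus 1, P0 villus 3 or P10 villus 2 (1.79, 1.70 and 1.93). Wnt targets rose in 16 of 22 (18 adjusted over the list alone), among them Notum (3.69 ± 0.60), with camera adjusted p = 3.27e-12 (adjusted p = 0.0254 with an estimated correlation). Imprinted and oncofetal genes fell in 10 and rose in 1 of 19 (11 and 1 adjusted over the list alone; camera adjusted p = 0.000329; adjusted p = 0.0486 with an estimated correlation), including Meg3 (-3.75 ± 0.71). Cell cycle genes rose in 14 and fell in 1 of 43 (22 and 2 adjusted over the list alone), Mki67 by 1.11 ± 0.25, with camera adjusted p = 0.00012 (adjusted p = 0.754 with an estimated correlation). Notch genes rose in 8 of 17 (9 adjusted over the list alone), among them Atoh1 (1.74 ± 0.35), with camera adjusted p = 0.00684 (adjusted p = 0.388 with an estimated correlation). Antimicrobial genes rose in 7 of 14 (7 adjusted over the list alone), among them the peroxide-forming oxidase gene Duox2 (3.42 ± 0.66), with camera adjusted p = 0.00104 (adjusted p = 0.298 with an estimated correlation). Goblet genes rose in 9 of 21 (9 adjusted over the list alone), Muc2 by 1.58 ± 0.27, with camera adjusted p = 0.000329 (adjusted p = 0.486 with an estimated correlation), and the call was lost without P0 villus 1 (0.397). In that library the goblet and Paneth list medians were -1.448 and -1.536 against the other P0 villus libraries.

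Hemidesmosome and basement membrane genes rose in 9 and fell in 2 of 23 in villus cells (12 and 2 adjusted over the list alone), with camera adjusted p = 0.00649 (adjusted p = 0.486 with an estimated correlation). Itga6 (1.16 ± 0.27) and Lama3 (2.04 ± 0.39) rose, Col4a1 (-4.26 ± 0.89) and Lama1 (-3.54 ± 0.70) fell, and Itgb4 had 0.12 ± 0.26 (adjusted p = 0.77). Rac1 had -0.35 ± 0.11 and Myh9 0.76 ± 0.20. Leaving out P0 villus 2, P0 villus 3 or P10 villus 2 ended both calls (Rac1 -0.34 to -0.35, Myh9 0.62 to 0.68), and P10 villus 1 or P10 villus 3 ended that of Rac1 (-0.33 and -0.36), as did library sizes alone as scaling (-0.14). Of 32 mature enterocyte genes 1 rose and 5 fell (0 and 5 adjusted over the list alone; camera adjusted p = 0.752), with Fabp1 at -1.81 ± 0.44, Alpi at -0.21 ± 0.38 (adjusted p = 0.727) and Vil1 at 0.24 ± 0.18 (adjusted p = 0.347). Lct (0.56 ± 0.42, adjusted p = 0.353), Fcgrt (0.03 ± 0.53, adjusted p = 0.978), Sis (1.11 ± 0.41, adjusted p = 0.0606) and Chga (-0.03 ± 0.44, adjusted p = 0.967) did not pass. Sis passed with DESeq2 (1.09), limma-voom (1.18) and library sizes alone as scaling (1.32). Prdm1 rose by 0.89 ± 0.19. Ass1 had -1.72 ± 0.58, lost without P0 villus 2, P0 villus 3, P10 villus 1 or P10 villus 2 (-0.84, -1.96, -1.55 and -1.59) or with GC and length offsets (-1.38), and Epcam 0.52 ± 0.14, lost without P0 villus 2, P0 villus 3 or P10 villus 2 (0.43, 0.44 and 0.48). Dclk1 had 20 counts over the P10 and 3 over the P0 libraries, a ratio of 5.36 (95% counting interval 1.59 to 28.2), and its call was lost without P0 villus 2, P0 villus 3 or P10 villus 3 (log2 1.91, 1.89 and 2.01). Of 14 immune markers 4 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.227). Without P0 villus 1 the enteroendocrine (0.00324) and cell junction (0.00839) lists passed, from 0.506 and 0.158. Other lists that passed with a library left out were fatty acid oxidation, BMP and stress without P0 villus 2 (0.000402, 0.0193 and 0.0488), stress without P0 villus 3 or P10 villus 1 (0.00262 and 0.0179), BMP without P10 villus 2 (0.0441) and ribosome biogenesis without P10 villus 3 (0.0273).

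**Figure D4:**
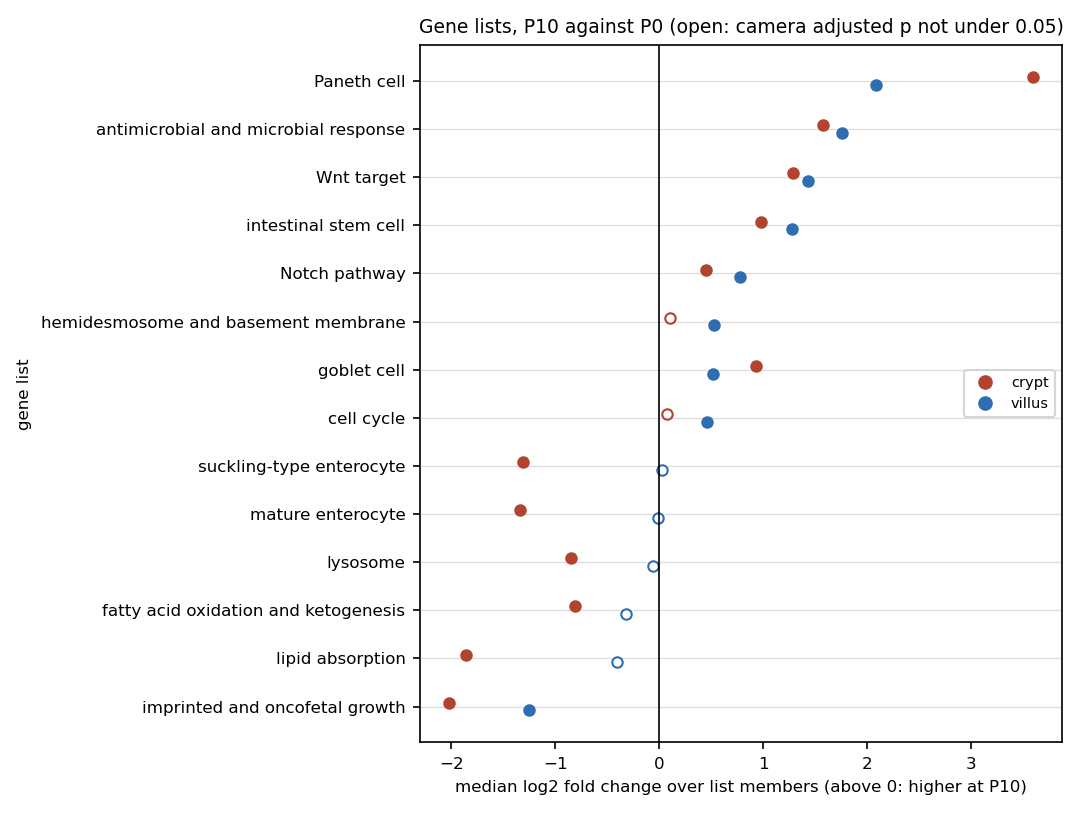
Median log2 fold change from P0 to P10 for each gene list past the threshold in crypt or in villus cells. The Paneth list has medians of 3.59 and 2.09 and the imprinted and oncofetal list of -2.02 and -1.26.

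In total 3558 genes differed between P10 and P0 villus cells, 1742 (49%) higher and 1816 lower at P10. Library sizes alone as scaling gave 78.8% higher, with the median of all genes at 0.20. The count was 6011 without P0 villus 1, 1968 without P0 villus 2, 1883 without P0 villus 3, 1771 without P10 villus 2, 6261 without both P0 replicate 1 libraries, and 828 when only the 6 libraries were fitted. Crypt and villus changes had a Pearson correlation of 0.707 over genes, with 1576 called in the same direction and 0 in opposite directions. Independent lists would share 305.4, a value that pairing of the populations at P10 can raise.

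No gene passed edgeR's test of whether the change from P0 to P10 differed between crypt and villus, and 1157 had an unadjusted p under 0.05. The limma-voom fit also gave 0, and DESeq2 gave 2, the cytochrome gene Cyp2c70 (-2.05) and the ephrin gene Efnb2 (-1.51), named after their values were seen. Without a filter on low counts edgeR gave the same 2 genes (adjusted p = 0.00292 and 0.024). The count was 1076 without P0 villus 1, of which 236 had a higher and 840 a lower change in crypt, and 1379 without both P0 replicate 1 libraries. With the replicate number as a block within age, which pairs the libraries at P10 and less clearly at P0, it was 166, Lct (-1.82) among them. It was 1, Cyp2c70 (-2.24), without P10 villus 1, and both genes also passed without P0 villus 1 (-2.09 and -1.67). For this contrast 23.9% of simulated 2-fold and 83.3% of 4-fold changes were recovered, which need not hold in these libraries.

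By list, mature enterocyte genes had a median difference of -1.35 and lipid absorption genes of -1.52 (crypt medians of -1.33 and -1.86, villus medians of -0.01 and -0.41, camera adjusted p = 1.49e-13 and 1.59e-11; adjusted p = 0.402 for each with an estimated correlation). No member passed over all genes, and 18 of 32 and 15 of 23 did when adjusted over the list alone. Lct had -1.86 ± 0.60 (adjusted p = 0.609) and Alpi -1.71 ± 0.55 (adjusted p = 0.609). Cell cycle genes had a median of -0.41 (camera adjusted p = 9.9e-07; adjusted p = 0.453 with an estimated correlation; 0 of 43 past in either way) and Paneth genes of 1.06 (camera adjusted p = 3.87e-05; adjusted p = 0.405 with an estimated correlation; 6 of 19 adjusted over the list alone). The mesenchyme list also varied within P0 crypt (2.30 in crypt 1, -2.38 in crypt 2).

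Between adjacent ages the fold changes followed GC content, with Spearman correlation over genes of -0.702 (crypt, P3 against P0), -0.673 (P6 against P3) and 0.806 (P10 against P6), and -0.693, -0.659 and 0.794 in villus. Against P0, P3 crypt cells had more Ifi44 (3.26 ± 0.53), Cnpy1 (3.16 ± 0.44) and the cytochrome gene Cyp3a25 (2.95 ± 0.77), and less Scd2 (-7.29 ± 1.58) and Scand1 (-7.99 ± 0.57). Reg3g (2.87 ± 1.16) lost its call without P0 crypt 1, P0 crypt 2, P3 crypt 2 or P3 crypt 3 (2.71, 2.47, 2.26 and 3.09). GC and length offsets ended the crypt calls of Cyp3a25 (2.09) and Reg3g (2.14). Gm23935 and Gm37194 had no counts in P3 crypt and were at least 1250-fold and 429-fold lower against a floor of 3 counts over the group. P3 villus cells had more Ifi44 (5.12 ± 0.54), Reg3b (4.39 ± 1.32), Ifit2 (4.33 ± 0.83) and Cyp3a25 (3.96 ± 0.77), and less Scand1 (-9.90 ± 0.64) and Scarna17 (-7.03 ± 0.57). Gm37194 was at least 774-fold lower, and Gm23935 had a single count against 6095 (ratio 5500, 95% counting interval 986 to 217000). The hemidesmosome list fell in crypt cells, with 15 of 23 lower and 1 higher (15 and 1 adjusted over the list alone), Lama5 by 3.34 on the log2 scale (camera adjusted p = 0.0433; adjusted p = 0.918 with an estimated correlation). It lost its call without P0 crypt 1 (0.0857), P0 crypt 3 (0.0609) or P3 crypt 1 (0.0634). Without P0 crypt 2, lipid absorption and mesenchyme passed in crypt (0.0448 each), and without P3 villus 2, MHC class II and stress in villus (0.0323 each).

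Against P3, P6 crypt had more Gm38393 (2.77 ± 0.55), Lcor (2.61 ± 0.56), Lnpep (2.54 ± 0.49) and A930004J17Rik (2.50 ± 0.39). It had less Ccdc124 (-4.29 ± 0.60) and Rps15 (-4.10 ± 0.56). Over 50 ribosomal protein genes, Rps15 lowest, crypt changes followed GC content (Spearman -0.61). Gm15487 and Erdr1 had 1 and 3 counts over the P6 crypt libraries, for ratios of P3 to P6 of 37.2 (95% counting interval 6.30 to 1510) and 17.5 (5.68 to 87.4). Both calls were lost without P3 crypt 1 (-2.96 and -2.70), that of Gm15487 with GC and length offsets (-3.91), and that of Erdr1 without P6 crypt 1 (-3.29). P6 villus had more Cysltr1 (3.03 ± 0.60), Gm38393 (3.01 ± 0.59), Slc5a8 (2.93 ± 0.38) and Arfgef3 (2.92 ± 0.56). It had less Rps15 (-4.93 ± 0.72) and Smim22 (-4.89 ± 0.81). Evpl and 2610305D13Rik had 2 counts each over the P6 villus libraries, for ratios of 38.5 (95% counting interval 10.5 to 322) and 718 (198 to 5930). The latter lost its call without P3 villus 1, P6 villus 1 or P6 villus 2 (-8.74, -9.41 and -9.53). Stem cell genes rose in 11 of 24 in both populations, with 1 lower in each (11 and 12 higher and 1 lower adjusted over the list alone), with camera adjusted p = 0.0288 in crypt and 0.00273 in villus (adjusted p = 0.849 and adjusted p = 0.941 with an estimated correlation). Lipid absorption fell in 12 and 13 of 23 (14 and 13 adjusted over the list alone), with adjusted p = 0.0118 and 0.00234, and lysosome genes in 15 and 17 of 28 with 1 higher (16 and 17 adjusted over the list alone), with adjusted p = 0.0288 and 0.00259 (adjusted p = 0.849 and adjusted p = 0.941 with an estimated correlation for each). Immune markers fell in 8 of 14 in crypt (9 adjusted over the list alone; adjusted p = 0.0288; adjusted p = 0.849 with an estimated correlation). In villus, mature enterocyte genes fell in 15 and rose in 2 of 32 (15 and 2 adjusted over the list alone; adjusted p = 0.0186) and MHC class II and interferon genes fell in 6 of 22 (6 adjusted over the list alone; adjusted p = 0.0279; adjusted p = 0.941 for both with an estimated correlation).

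Leaving out P3 crypt 2 ended the crypt calls of these days for stem cell (0.111), lipid absorption, lysosome and immune genes (0.0555 each), and P6 crypt 1 those for stem cell, lipid absorption (0.0868 each), lysosome and immune genes (0.106 each). Leaving out P3 crypt 1 ended the lysosome call (0.0931). In villus, mature enterocyte genes lost their call without P3 villus 2 (0.0773) or P6 villus 1 (0.0799). MHC class II and interferon genes lost theirs without P3 villus 1 (0.0546), P3 villus 2 (0.0798) or P6 villus 1 (0.578). Calls were gained in crypt by mature enterocyte genes without P3 crypt 3 (0.0118), P6 crypt 2 (0.0349) or P6 crypt 3 (0.0229), and by MHC class II and interferon genes without P3 crypt 3 (0.0391) or P6 crypt 2 (0.0349). In villus Wnt targets gained theirs without P3 villus 3 (0.0127) or P6 villus 2 (0.0174).

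From P6 to P10, Scand1 went from 2 counts over the P6 crypt libraries to 4130 (ratio 1640, 95% counting interval 453 to 13500), Gm37194 from 1 to 1620 (1290, 230 to 50800) and Erdr1 from 3 to 2588 (685, 234 to 3320), while Gm26917 rose by 9.17 ± 0.66. In villus Scand1, Gm37194 and Erdr1 had no counts at P6 and were at least 863-fold, 354-fold and 222-fold higher at P10 against a floor of 3 counts over the group, and Gm26917 rose by 10.66 ± 0.90. The largest falls in crypt, by the rule used from P0 to P10, were Cd36 (-3.68 ± 0.75), Abcb11 (-3.67 ± 1.43), the cytokine gene Il1a (-3.53 ± 0.68) and Mgat4c (-3.47 ± 0.41), and in villus Abcb11 (-3.99 ± 1.23), Il1a (-3.70 ± 0.63), Tmem263 (-3.60 ± 0.45) and Gm8822 (-3.42 ± 0.69). Abcb11 lost its crypt call without P6 crypt 2, P10 crypt 1 or P10 crypt 2 (-2.97, -3.38 and -3.62) and its villus call without P6 villus 2 (-2.68). With GC and length offsets the calls of Cd36 (-1.90) and Abcb11 (-2.73) in crypt and of Abcb11 (-2.90) and Gm8822 (-1.53) in villus were lost. Paneth genes rose in 16 and fell in 2 of 19 in crypt cells (16 and 2 adjusted over the list alone; median 2.73, or 2.54 with a member at 0 set to its bound; camera adjusted p = 0.0369; adjusted p = 0.979 with an estimated correlation). The call was lost without P6 crypt 3 (0.104), and without P6 crypt 2 goblet genes passed (0.0498).

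The numbers of genes past the threshold were 8531 (P3 against P0), 7392 (P6 against P3) and 11469 (P10 against P6) in crypt and 9924, 7953 and 11395 in villus. With an offset for GC content and transcript length they were 4512, 4209 and 7250 in crypt and 6559, 4901 and 7035 in villus. Of these, 3275, 3094 and 5214 in crypt and 4868, 3585 and 5123 in villus were called in the same direction without the offset, while 151, 104 and 758 and 329, 133 and 687 were called in opposite directions. The villus count from P3 to P6 was 4264 without P6 villus 1. With library sizes alone as scaling, the share of calls that were higher went from 42% to 18.8% (crypt, P6 against P3) and from 53.7% to 70.3% (P10 against P6). In villus it went from 45.1% to 35.3% (P6 against P3) and from 51.7% to 67.9% (P10 against P6). The median of all genes moved to -0.40 and 0.68 in crypt and to -0.25 and 0.71 in villus.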

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

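The tests of GC content, library size, P0 replicate 1 and the Paneth list, and the fits without both P0 replicate 1 libraries or without the P3 and P6 libraries, were chosen only after the results were seen.

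For 13 gene lists the change from P0 to P10 differed between crypt and villus by camera, while the number of single genes past edgeR's test was 0. Of absorptive lists, mature enterocyte genes had a median log2 difference of -1.348 (adjusted p = 1.49e-13), lipid absorption -1.524 (1.59e-11), suckling-type enterocyte -1.018 (6.95e-06), lysosome -0.666 (1.41e-06) and fatty acid oxidation and ketogenesis -0.411 (0.000395). Paneth genes had 1.062 (3.87e-05), enteroendocrine genes 0.807 (0.000395) and cell cycle genes -0.412 (9.9e-07). Cell junction genes had -0.340 (0.00016), hemidesmosome and basement membrane genes -0.339 (0.017), MHC class II and interferon genes -1.078 (0.00173), immune markers -1.855 (0.000878) and mesenchyme markers -1.997 (0.0364). With an estimated correlation none of the 13 passed (adjusted p = 0.402 to 0.626), nor did any by fry in either form. Adjusted over the list alone, 18 of 32 mature enterocyte, 15 of 23 lipid absorption, 6 of 19 Paneth, 2 of 13 suckling-type, 2 of 28 lysosome and 2 of 14 immune genes passed, and none of the other 7 lists' members.

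Single P0 libraries decided several of these calls. Without P0 crypt 1 the hemidesmosome (0.216), MHC class II (0.229) and mesenchyme (0.529) calls were lost, and without P0 villus 1 the MHC class II (0.0599), immune (0.176) and mesenchyme (0.563) calls. Without both, the lysosome (0.149), MHC class II (0.501), immune (0.52) and mesenchyme (0.898) calls were lost. The hemidesmosome call was also lost without P0 villus 2 (0.0655), P0 villus 3 (0.0533) or P10 villus 3 (0.0699), the fatty acid oxidation call without P0 villus 2 (0.136), and the mesenchyme call without P10 crypt 2 (0.516), P10 villus 1 (0.306) or the P3 and P6 libraries (0.0667). Stem cell genes (0.0522 in the full data) passed as lower without P0 crypt 1 (0.0117), P0 villus 1 (0.0107), P10 crypt 1 (0.0276), P10 crypt 2 (0.0375), P10 villus 3 (0.000817) or both P0 replicate 1 libraries (0.00476). Imprinted genes passed without P0 crypt 3 (0.0261), P0 villus 2 (0.0335), P10 crypt 3 (0.0385) or P10 villus 2 (0.0495). Goblet genes passed without P0 villus 1 (0.00214) or both replicate 1 libraries (0.0216), BMP genes (0.0366) and endothelial markers (0.0419) without P0 villus 2, and stress genes without P0 villus 3 (0.0399). Of 200 regroupings of the 12 libraries 100 were drawn, and 33 of them, the real grouping included, had as many genes at an unadjusted p under 0.05 as the real 1157, with 5916 (2638 past the adjusted threshold) as the highest other. They mix ages within a population, so they carry the change with age shared by the populations into the contrast and break the P10 pairs, and do not decide whether chance can be excluded.

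The P0 replicate 1 libraries stood apart from the other P0 libraries of their population, and P0 crypt 2 lay apart the other way, with mature enterocyte, immune and mesenchyme medians of -1.011, -1.221 and -2.382. Over genes that differ between the populations at other ages, P0 crypt 1 lay at 0.643 on a scale from villus (0) to crypt (1). The 3 other versions of this test gave 0.613, 0.584 and 0.562. This goes with CD44-negative enterocytes in it but excludes no difference in maturity between animals. Against the other P0 crypt libraries its secretory medians went both ways (goblet -0.42, where P0 villus lay at 1.398, and enteroendocrine 1.421). Its cell cycle median, which CD44-negative cells would lower, was only -0.175 (mature enterocyte 1.266). Such cells cannot account for its mesenchyme genes, 2.296 (log2) above those libraries while P0 villus lay at -1.263. GC and length bias does not account for the absent interaction calls, as offsets for it left 0. P0 villus 1 had goblet, enteroendocrine and Paneth medians of -1.448, -1.656 and -1.536 against the other P0 villus libraries and a mature enterocyte median of 0.151, so it may hold fewer secretory cells, an explanation drawn from these same lists, and it was also lower in mitochondrial share (5.14% against 10.68% and 11.67%), share of the 10 highest genes (8.82%, 14.14% and 15.45%) and reads outside genes (8.87%, 12.02% and 13.46%). Whether it also held CD44-positive cells stays open, as its median position over genes higher in crypt was 0.195 (quartiles 0.0975 and 0.31) with a minimum 2-fold difference and 0.13 without it, and over genes higher in villus 0.325 and -0.0332.

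The P3 and P6 libraries lay apart from the P0 and P10 libraries, with lower GC content. Among 50 genes of cytosolic ribosomal proteins, which code for parts of a single complex, the crypt change from P6 to P10 had a Spearman correlation of 0.729 with GC content over genes (permutation p = 1e-05, two-sided, the smallest that 1e+05 permutations can give), so GC bias may be part of the pattern. A smooth trend on GC content and length is not the whole of it, since with it removed the changes from P0 to P3 and from P6 to P10, which share no library, still had a correlation over genes of -0.52 in crypt (-0.732 before) and -0.586 in villus (-0.766 before). Library size does not account for it, as 11169 genes were called between P10 and P6 crypt with all libraries thinned to the smallest total. A library batch shared by P3 and P6 cannot be told apart from age, as a gap of 1.83 percentage points of mean GC content parted all P3 and P6 from all P0 and P10 libraries, and age itself stays open as untested.

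At P0 the Paneth list was higher in the CD44-negative cells, whereas Paneth cells are known from the CD44-positive base of adult crypts. Reads shared between defensin copies do not account for all of it, as the 11 members that are not defensins had a median log2 difference of -1.459 (4 past the threshold higher in villus, 1 in crypt), beside -2.298 for 8 defensins. Paneth cells sorted as CD44-negative, and secretory cells that carry these transcripts without CD44 at birth, stay open and were not tested.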

How the results depend on the processing

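Settings given above as chosen after seeing the data, tests of other splits and list tests with the block within age were not fixed before. The remaining settings were. For the counts of genes, scaling by DESeq2's size factors or library size, the filter of 1 CPM in 3 libraries, limma-voom, thinning and leaving out mitochondrial genes or the P3 and P6 libraries kept each within 1.5 times its value. Fitting only the groups compared gave 798 between crypt and villus at P0 and 6085 at P10, 828 in villus from P0 to P10 and 636 shared calls. GC and length offsets gave 4512, 4209 and 7250 for adjacent ages in crypt and 6559, 4901 and 7035 in villus, and with the replicate block within age 6362 at P10. Without both P0 replicate 1 libraries 6261 genes were called in villus from P0 to P10 and 1379 in the interaction. The interaction had 2 calls with no filter on low counts, 2 with DESeq2 and 166 with the replicate block within age. The cause was not tested for any of these changes.

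Leaving out a library in turn gave, from lowest to highest, 2421 to 6382 calls between crypt and villus at P0, 4010 to 5181 at P3, 1223 to 2971 at P6 and 2304 to 3495 at P10. The shared calls ranged from 770 to 2083. From P0 to P10 the ranges were 1454 to 2561 in crypt and 1771 to 6011 in villus. For adjacent ages they were 6916 to 8608, 5112 to 7490 and 10593 to 10939 in crypt, and 8651 to 10348, 4264 to 8121 and 9521 to 10997 in villus. The interaction ranged from 0 to 1076, the latter without P0 villus 1. Where P6 villus is left with a single library, it is assumed to vary like the other groups.

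Of the list tests, camera called 15, 13, 13 and 11 lists between crypt and villus at P0, P3, P6 and P10, 12 in crypt and 9 in villus from P0 to P10, and 13 in the interaction. With an estimated correlation it called 0, 0, 0, 0, 3, 2 and 0. Mixed fry, which asks for change in either direction, called 26, 26, 22, 26, 23, 20 and 0, and directional fry called 0 in the interaction. With a library left out the camera counts were 11 to 14, 13 to 13, 13 to 14, 11 to 14, 13 to 16, 10 to 12 and 11 to 14. With the GC and length trend removed, no called list changed direction and MHC class II genes in villus from P3 to P6 lost their call (adjusted p = 0.0881). Cell junction genes at P0 (0.0347) and ribosome biogenesis genes in crypt from P0 to P10 (0.0154) gained theirs. Among adjacent ages, Wnt targets passed as higher at P3 than P0 (0.000485 in crypt, 0.00504 in villus) and at P6 than P3 (0.000225 and 7.05e-05), suckling-type genes as lower at P6 than P3 (0.0226 and 0.0154), and stem cell genes in crypt as higher at P3 (0.0212). Mature enterocyte genes in crypt passed as lower at P6 (0.0105), and at P10 goblet genes passed as higher and imprinted genes as lower than at P6 (0.0212 each). In villus at P3 ribosome biogenesis passed as lower (0.00402), lysosome (0.00452) and MHC class II genes (0.00146) as higher, and at P10 cell cycle (0.0131), ribosome biogenesis (0.0195) and Paneth genes (0.0412) as higher than at P6. Without both P0 replicate 1 libraries, fatty acid oxidation (0.293), immune (0.277) and mesenchyme genes (0.699) lost their calls at P0 and goblet genes in villus over age (0.441), while cell junction genes passed at P0 (0.00963). Without the P3 and P6 libraries, stress genes passed in villus from P0 to P10 (0.0415). The cause was not tested.

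The named genes gave 379 pairs of gene and comparison and 7312 values under other settings, of which 6923 kept direction and side of the threshold, 330 lost a call, 59 gained a call and 0 reversed. Of the pairs, 269 kept both throughout. Leaving out a library lost 179 and gained 10, fitting only the groups compared lost 33 and gained 5, and no filter lost 34 and gained 2. Library size scaling lost 16 and gained 4, limma-voom lost 14 and gained 2, GC and length offsets lost 10 and gained 3, and DESeq2 lost 6 and gained 6. DESeq2's size factors in edgeR and the filter of 1 CPM changed none. Of the calls given above, library size scaling ended Lct at P0 and in crypt over age, Ass1 in villus over age, Reg3g in crypt at P3 and Abcb11 in crypt at P10 against P6. Limma-voom ended Hspg2, Evpl and Pkmyt1 at P6, Abcb11 in both populations over age and in crypt at P10 against P6, Ass1 in villus, Reg3g in crypt at P3, and Erdr1 and 2610305D13Rik at P6 against P3. DESeq2 ended Dclk1, Reg3b and Reg3g in villus over age and Reg3g in crypt and Reg3b in villus at P3. Fitting only the groups compared ended, among others, Chga, Lct, Itga6, Myh9 and Fabp1 at P0, Col4a1 in crypt and Scd2 and Abcb11 in villus over age. Gained were Epcam at P10 (library size), Lyz1 at P0 and Fcgrt in crypt over age (DESeq2), Fcgrt at P0 (limma-voom), and Itgb4 and Sis at P10 (only the groups compared).

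Whether replicate numbers pair the libraries at P0 is unclear. Same-numbered crypt and villus libraries had correlations of -0.151, 0.373 and 0.032, not all over 0.1, and the highest was 0.408, of crypt 3 with villus 1, but pancreatic markers were high in crypt 3 (3.366) and villus 3 (2.045) alike. Nor could they be judged at P6, with 2 pairs (0.485 each). Between ages the correlations ran from -0.283 to 0.222 in crypt and from -0.324 to 0.2 in villus. With the replicate block within age the counts were 5942 at P0, 6445 at P3, 3923 at P6 and 5160 at P10. At P0 the block gained the calls of Lyz1 (-1.02), Alpi (-1.02), Fcgrt (-1.79) and H19 (-1.50), and in the interaction those of Lct (-1.82), Cyp2c70 (-1.999) and Efnb2 (-1.52). With the replicate number as a block over all libraries, mesenchyme genes in crypt from P0 to P10 (adjusted p = 0.0235) and stem cell genes in the interaction (adjusted p = 0.047) passed. It lost the calls of Lct at P0 (-1.19) and in crypt over age (-1.33), Ass1 in villus (-1.67), Rac1 (-0.33) and Myh9 (0.61) in crypt over age, and Reg3g in crypt from P0 to P3 (2.51). Apart from these and the calls given for P3 and P10, the block changed no other printed call.

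The splits of the 6 libraries of a comparison number 10, too few for a share under 0.05, and in each comparison only 1, the real one, gave as many calls. The real value and the highest of the others were 4427 and 2301 at P0, 5482 and 603 at P3, and 4011 and 0 at P10 between crypt and villus. They were 2829 and 0 for crypt and 3558 and 1482 for villus from P0 to P10, 8531, 7392 and 11469 against 0 for adjacent ages in crypt, and 9924 against 0 in villus from P0 to P3. The split with 2301 calls sets P0 crypt 1 with P0 villus 2 and 3, and that with 1482 sets P0 villus 1 with P10 villus 2 and 3. At P3 and P10, the highest of the 3 other splits that part all pairs gave 0.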

Other observations

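The test of lipid supply in the P0 replicate 2 libraries, with its list of sterol and fatty acid synthesis genes, was chosen only after those libraries had been seen to differ.

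Scd2, which had the largest fall from P0 to P10 in both populations among genes with a mean log2 CPM of at least 3 whose groups did not overlap, varied widely within P0. Its CPM was 1390, 2640 and 94.3 in P0 crypt 1, 2 and 3, and 88.5, 3020 and 76.8 in P0 villus 1, 2 and 3. The lipid transporter gene Mfsd2a had 3.64 and 9.19 in the replicate 2 libraries and 81.1 to 252 in the other P0 libraries, and the kinase gene Pdk4 had 23.2 and 16.6 against 111 to 276. These genes were singled out after their values were seen. A candidate explanation is a difference in lipid supply, such as less milk taken before collection. It requires higher synthesis and lower oxidation genes in both replicate 2 libraries. The sterol and fatty acid synthesis list had medians of 0.584 in crypt 2 (24 of 27 genes above 0) and 1.432 in villus 2 (26 of 27), against the other P0 libraries of each population. The fatty acid oxidation list had -0.93 and -0.786, with 17 of 19 genes below 0 in each. These values go with the explanation, but the list was written after part of them had been seen, and another litter or hour of collection was not tested.

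Pancreatic acinar markers had medians of 3.366 in P0 crypt 3 and 2.045 in P0 villus 3 (log2, against the other P0 libraries of each population). In the enteroendocrine list, Gip (3.81) and Nts (-3.24) had opposite mean log2 differences between crypt and villus over the 4 ages.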
